A study of Mus musculus with 6 samples.

How the data were processed

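The study measured messenger RNA in mouse cardiac ventricles by short-read sequencing. Per the labels, the mice were on the C57BL/6 background, total RNA was extracted from the tissue, and Illumina libraries were made from it. There were 6 groups, formed by 2 genotypes (Klf15 wild type, WT, and Klf15 loss of function, KO) and 3 ages (postnatal day 10, P10; 4 weeks, 4w; 20 weeks, 20w). Each group had 3 replicate libraries, which gave 18 libraries in all. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. How the loss of function was made, the sex of the animals and the sequencing batches are not given in the sources used here.

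The deposited values are a signal per gene, namely read counts that the authors divided by 1 size factor per library (normalized counts of DESeq2, per the file name). Per the submitters' processing notes, the reads were handled with Bowtie2 2.0, the genome build mm9 and DESeq2. The notes give neither the role nor the order of these tools. The read counter, its strand setting and the gene annotation are not given in the sources used here. Every value in a library was a whole multiple of the step that 1 read is worth there. Dividing by that step gave whole reads for 100.0% of the values, within a tolerance of 0.001 reads. The recovered libraries held 9504538 to 29278351 reads assigned to genes. Of the 24391 gene entries, 27 had names turned into dates by a spreadsheet. Those entries were kept in the library totals (at most 0.204% of a library's reads) but not interpreted. A genome annotation of another mouse build (GRCm38) was used here for gene neighbourhood, GC content and transcript length (98.3% of the entries matched), and no coordinates are given.

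Values were analysed as log2(value + 1), with a pseudocount of 1. A fold change is therefore on that scale and understates the change of genes with low values. Genes with a mean value of at least 10 over the 18 libraries were tested, which left 13032. One limma 3.58.1 model (R 4.3.3) with 6 group means was fitted to the 18 libraries, which share an estimate of the spread per gene, with empirical Bayes moderation along a mean trend. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Contrasts compared KO with WT at each age and averaged over the ages. Others compared the KO effect between each pair of ages (an interaction) and WT between adjacent ages. The positive sign always means higher in KO, at the later age, or in the KO effect at the later age. A fold is given as the size of the change. SE is the model's standard error, and levels are means ± SD of 3 libraries.

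Before the data were examined, 33 gene lists were fixed from textbook knowledge, 19 of pathways and 14 of cell types. They held 613 entries, of which 611 were found in the table. The Wnt/beta-catenin targets included Shisa3, the gene that the series title names. The pathway lists were branched-chain amino acid catabolism, fatty acid uptake and oxidation, glucose uptake and glycolysis, oxidative phosphorylation, Wnt/beta-catenin targets, Wnt ligands and receptors, secreted Wnt antagonists, the fetal and stress sarcomere programme, mature excitation and calcium handling, and the circadian clock. Further ones were glucocorticoid-responsive genes, extracellular matrix and fibrosis, vascular growth and tip cells, cell cycle, interferon response, immediate early genes, the integrated stress response and one-carbon metabolism, heat shock and chaperones, and atrophy and the ubiquitin-proteasome system. The cell type lists were markers of cardiomyocytes, fibroblasts, endothelium, smooth muscle and pericytes, macrophages, the atria, mesothelium and epicardium, and nerve and Schwann cells. Those of lymphocytes, adipocytes, erythroid cells, skeletal muscle and lung epithelium had fewer than 5 tested members and were not tested, and a sex-linked list served as a check of the libraries. The 27 lists with at least 5 tested members were tested with limma's camera with a preset inter-gene correlation of 0.01, which asks whether a list moves relative to the other genes. The adjusted p with a correlation estimated for each list is given beside it. A count "adjusted over the list alone" uses Benjamini-Hochberg adjustment among the members of that list.

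The genes named follow a rule fixed at the same time. It takes Klf15 and Shisa3, then in each comparison the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 50 and groups that do not overlap. It adds up to 4 members with the smallest adjusted p per list discussed, and up to 4 genes per direction for each interaction. Gene models without an ordinary name were skipped, and some results that the rule selects are not reported here. Where no member of a list was called, up to 2 members are given as values. Which lists and members are discussed was chosen after the results were seen. The direction of the KO effect relative to maturation was tested with a correlation across genes and an exact permutation of the 6 libraries of an age.

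The test was checked on simulated reads for the 13032 genes, drawn from negative binomial distributions with the group means, the size factors and the dispersion of each gene, with 50 changed genes per size. At P10, 72% of the genes changed by a log2 fold change of 1 and 100% of those changed by 2 were called. At both 4w and 20w the shares were 80% and 100%. False calls made up 3.75% of the calls at P10, 5.03% at 4w and 6.7% at 20w. Replicates were compared pairwise, and no 2 libraries agreed within sampling noise (the smallest chi-square per degree of freedom was 4.92).

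The alternatives tried were other pseudocounts, filters, scalings and fits, library weights, a replicate block, an Xist covariate, other thresholds and other set tests. Each library was also left out in turn. Tests of the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0 were among those set in advance. Removal of GC content and length trends, a covariate from the residuals, and the analysis without the 4 libraries highest in the ribosomal RNA gene Rn45s were added after seeing the data.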

Results

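Gene expression was profiled in cardiac ventricles of WT and Klf15 KO mice at P10, 4w and 20w, with 3 libraries per group. KLF15 is a zinc finger transcription factor of the Krüppel-like family with known roles in amino acid and lipid metabolism. The series title links KLF15 and Wnt signalling to Shisa3, a member of the Shisa family of Wnt and FGF signalling modulators. The libraries held 9504538 to 29278351 reads assigned to genes. Age was the main axis of variation, and the first principal component carried 68.4% of the variance. In the second 4w KO library, 30.8% of the reads fell on the ribosomal RNA gene Rn45s and 1.78% on Lars2. The next highest shares of Rn45s were 2.72% in the second 20w WT library, 1.74% in the second 4w WT library and 1.7% in the second 20w KO library.

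Klf15 was lower in every KO library than in any WT library at each age. Its level fell from 149.7 ± 12.9 in WT to 22.5 ± 4.4 in KO at P10 (SD, n = 3 libraries each; log2 fold change -2.69 ± 0.2 SE, limma adjusted p = 1.3e-07). At 4w it was 1078.3 ± 211.6 in WT and 42.2 ± 13.2 in KO (-4.67, adjusted p = 5.1e-12), and at 20w 1021.5 ± 74.3 and 40.0 ± 6.3 (-4.65, adjusted p = 3.7e-12). In WT hearts Klf15 rose by 2.82 on the log2 scale from P10 to 4w (adjusted p = 6.3e-10) and did not pass the test between 4w and 20w (-0.06, adjusted p = 0.85). Shisa3 was at 62.8 ± 23.5 in WT and 29.4 ± 9.3 in KO at P10 (-1.05 ± 0.31 SE, adjusted p = 0.091). At 4w the levels were 54.4 ± 28.1 and 64.6 ± 5.4 (0.35, adjusted p = 0.63). At 20w Shisa3 was 2.17-fold higher in KO, at 90.1 ± 29.7 against 39.8 ± 3.9 (1.12, adjusted p = 0.033). The KO effect on Shisa3 at 20w differed from that at P10 by 2.17 on the log2 scale (adjusted p = 0.0083). The call at 20w was lost when any of 5 of the 6 libraries was left out (adjusted p = 0.17 without the third KO library), and at P10 a call appeared with edgeR (-1.16) and DESeq2 (-1.12).

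**Figure D1:**
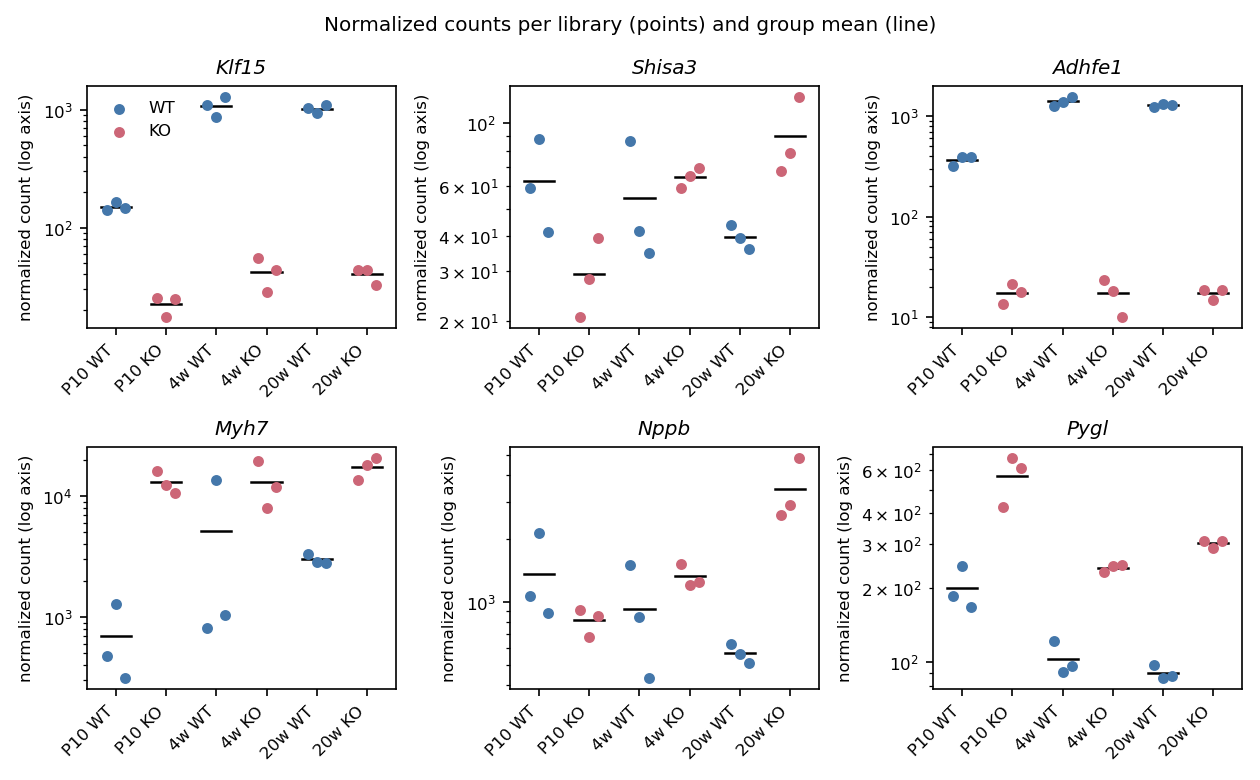
Normalized counts per library on log axes for 6 genes in the 6 groups, with WT in blue, KO in red and a line at each group mean. Klf15 and Adhfe1 were lower in all KO libraries at each age, and the second 4w WT library reached 13491.4 for Myh7, within the KO range.

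At P10, Adhfe1 and Cyfip2 were far lower in KO hearts and Myh7 far higher. Myh7, the slow beta myosin heavy chain of the fetal ventricle, stood at 13019.7 ± 2784.1 in KO against 691.5 ± 525.0 in WT (22.3-fold, log2 fold change 4.48 ± 0.68 SE, adjusted p = 0.00074). Pygl, the liver isoform of glycogen phosphorylase, rose from 198.6 ± 40.4 to 567.4 ± 128.0 (1.5, adjusted p = 1e-05). Rph3al, a Rab effector of exocytosis, rose by 1.45, Pdzrn4 by 1.35 and Adra1a, the alpha-1A adrenergic receptor, by 1.14. Rprl3, an RNase P RNA entry with near-identical copies in the genome, had the highest fold change (6.93), and its count is uncertain because reads can be shared between copies. Among called genes with a mean of at least 50 and groups that did not overlap, the lowest fold change was that of Adhfe1, a mitochondrial hydroxyacid-oxoacid transhydrogenase, which fell from 366.4 ± 39.7 to 17.5 ± 3.8 (-4.33 ± 0.21 SE, adjusted p = 1.4e-10). Cyfip2, a subunit of the WAVE actin regulatory complex, fell from 2950.9 ± 217.6 to 216.5 ± 36.4 (-3.77, adjusted p = 4.3e-06). At 4w the groups overlapped for Cyfip2 (894.5, 1469.0 and 4178.6 in WT, 791.5 to 1826.2 in KO), and also for Myh7 and Rprl3. The hydrolase gene Abhd1 fell by 2.94 on the log2 scale, the neurotrophin gene Bdnf fell by 2.27 and the proton pump subunit gene Atp6v0e2 fell by 1.78.

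Of 22 tested members of branched-chain amino acid catabolism, 10 fell at P10 and none rose (14 fell adjusted over the list alone). Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, was 2.05-fold lower (adjusted p = 3.7e-06), Aldh6a1 1.92-fold (6.2e-06), Ivd 1.66-fold (0.00015) and Mut 1.48-fold (0.00033). The list moved down in camera (adjusted p = 2.1e-17), but its adjusted p = 0.13 with an estimated correlation. In the cell cycle list 5 of 30 members fell over all genes tested and 21 adjusted over the list alone (camera adjusted p = 2.3e-17; adjusted p = 0.13 with an estimated correlation). The ribonucleotide reductase genes Rrm2 and Rrm1 were 2.71-fold and 1.53-fold lower, Ccne2 1.84-fold and Top2a 1.88-fold. None of 35 genes of fatty acid uptake and oxidation was called (camera adjusted p = 0.53), with Echs1 at -0.28 and Slc27a1 at 0.39. Heat shock and chaperones had 3 of 17 members lower, among them Hspb6 (1.95-fold, adjusted p = 0.0016), Hspd1 and Cryab (camera adjusted p = 0.00083; 0.52 with an estimated correlation). Glucose uptake and glycolysis had 2 of 21 lower, Hk2 (1.71-fold) and Eno3 (1.25-fold) (camera adjusted p = 4.1e-05; adjusted p = 0.34 with an estimated correlation). Hk2 lies within 10 Mb of Klf15, a region taken up below. Oxidative phosphorylation had 2 of 30 lower, Cox6a2 (1.5-fold) and Sdhb (1.28-fold) (0.014; adjusted p = 0.84 with an estimated correlation). In the excitation list Kcnq1 rose and Kcnip2 fell (camera up, adjusted p = 0.014; adjusted p = 0.53 with an estimated correlation).

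Some lists of other cell types also passed camera with the preset correlation at P10. However, 4 of 10 splits of the libraries between the groups, described below, called as many lists as the real 9. The macrophage list was lower with none of 18 members called (median log2 fold change -0.22, adjusted p = 0.00059; adjusted p = 0.26 with an estimated correlation), as was the interferon list with none of 22 (-0.2, 0.012; adjusted p = 0.84 with an estimated correlation). Timd4, a receptor of resident macrophages, had a value of -1.64 (adjusted p = 0.054). Smooth muscle and pericyte markers were higher, with Abcc9 called among 12 (1.23-fold, camera adjusted p = 0.0056; adjusted p = 0.34 with an estimated correlation). Cardiomyocyte, fibroblast and endothelial markers had no called member at P10 (adjusted p = 0.53, 0.58 and 0.18). The P10 libraries held both Xist (8606.7 ± 3028.1 in WT, 5657.0 ± 904.2 in KO) and the Y-linked gene Ddx3y (819.6 ± 256.2 in WT, 969.8 ± 385.6 in KO). Xist was at most 9.4 in any 4w or 20w library.

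In all, 295 of 13032 genes were called at P10 in limma, 77 higher and 218 lower. Over the alternative fits and scalings the count lay between 109 (libraries scaled to a common total) and 1384 (library quality weights), and without single libraries it went down to 110 (without the third WT library). Among the genes named, the calls of Pdzrn4, Adra1a, Top2a, Eno3, Sdhb, Hspd1, Cryab, Kcnq1, Kcnip2 and Abcc9 were lost without at least 1 library, with a highest adjusted p = 0.21 for Cryab (without the second WT library) and 0.2 for Sdhb (without the third). The lists of oxidative phosphorylation (adjusted p = 0.63 without the third KO library), excitation (0.56 without the second WT library) and interferon (0.22 without the third WT library) were lost in the same way.

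At 4w, genes of fatty acid oxidation were lower in KO hearts together with those of branched-chain amino acid catabolism. Of 35 tested genes of fatty acid uptake and oxidation 27 fell and none rose (30 fell adjusted over the list alone; camera adjusted p = 1.8e-36; adjusted p = 0.019 with an estimated correlation). The acyl-CoA thioesterase Acot1 fell from 112.5 ± 46.1 to 15.7 ± 4.1 (log2 fold change -2.7 ± 0.32 SE, adjusted p = 1.5e-05). Echs1, the enoyl-CoA hydratase, was 1.81-fold lower (5478.4 ± 452.0 to 3020.9 ± 227.3), the carnitine-acylcarnitine carrier Slc25a20 1.76-fold and the thiolase Acaa2 1.77-fold. Of 22 genes of branched-chain amino acid catabolism 14 fell and none rose (16 adjusted over the list alone; camera adjusted p = 2.5e-28; adjusted p = 0.019 with an estimated correlation). Aldh6a1 was 3.29-fold lower (5714.9 ± 654.9 to 1729.8 ± 50.5), Bckdhb 3.11-fold, Dbt 2.46-fold and Mut 1.99-fold.

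Among called genes with a mean of at least 50 and groups that did not overlap, the lowest fold changes at 4w after Adhfe1 (-6.33 ± 0.21 SE, adjusted p = 1e-13) and Klf15 included Bdnf (-3.7), Gstm2, a glutathione S-transferase (206.8 ± 20.4 to 17.1 ± 4.9, -3.55), and Bdh1, the ketone body hydroxybutyrate dehydrogenase (341.9 ± 98.8 to 37.1 ± 5.1, -3.14). Esr1, the estrogen receptor alpha gene, had a fold change of -6.12 that came from the WT libraries, which held 30245.9, 5205.2 and 345.6, while every other library held at most 77.1. The highest under the same limits were Phlda1 (1.49 ± 0.17 SE, 114.4 ± 30.5 to 316.8 ± 30.6), Hspa8, the constitutive 70 kDa heat shock cognate (1.27, 1093.4 ± 187.1 to 2628.4 ± 287.3), Pygl (1.24), the epsin gene Epn3 (1.09), Plekhh1 (1.01) and the transcription factor gene Sp2 (0.97). Myh7, a member of the fetal and stress list, was called (2.45, adjusted p = 0.038), but its WT libraries held 803.5, 13491.4 and 1040.3. The call was lost without any of 5 of the 6 libraries (adjusted p = 0.18 without the first or the third WT library) and with edgeR and DESeq2.

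Glucocorticoid-responsive genes had 3 of 19 members lower at 4w, Glul (1.62-fold), Sult1a1 (1.45-fold) and Klf9 (1.25-fold) (camera adjusted p = 0.0017; adjusted p = 0.53 with an estimated correlation). In the excitation list 4 of 22 rose and 1 fell, with the L-type calcium channel gene Cacna1c (1.43-fold), the connexin gene Gja1 (1.43-fold) and Hcn2 (1.49-fold) higher and the potassium channel gene Kcnv2 2.46-fold lower (camera up, adjusted p = 0.045; adjusted p = 0.57 with an estimated correlation). Fibroblast markers had 2 of 14 lower, Dcn (1.27-fold) and Dpt (1.26-fold) (camera adjusted p = 0.041; adjusted p = 0.55 with an estimated correlation). Oxidative phosphorylation had 2 of 30 lower, Cox6a2 (1.92-fold) and Sdhb (camera adjusted p = 0.11). The gluconeogenic and glycolytic regulator Pfkfb1 fell from 68.6 ± 11.6 to 10.3 ± 3.3 (-2.64), while Hk1 and Pfkfb2 rose by 0.34 and 0.31, and the glucose list as a whole did not pass (adjusted p = 0.31). None of 19 Wnt/beta-catenin targets was called (camera adjusted p = 0.23). Axin2, a feedback target of the pathway, was at 83.2 ± 9.6 in WT and 124.6 ± 23.4 in KO (0.57, adjusted p = 0.058), and Cd44 at 369.8 ± 88.0 and 560.2 ± 116.8 (0.6, adjusted p = 0.062). Neither the 18 Wnt ligands and receptors (adjusted p = 0.37) nor the 9 secreted antagonists (adjusted p = 0.41) had a called member.

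In all, 736 genes were called at 4w, 390 higher and 346 lower. With libraries scaled to a common total, which includes Rn45s, the median of all genes moved to -0.236 and 3.1% of the 617 called genes were higher, against 53.0% in the main result, so calls of higher genes hold relative to the deposited scaling. Without the 4 libraries highest in Rn45s 212 genes were called, and without single libraries 373 (without the first KO library) to 675. The calls of Sp2, Sult1a1, Klf9, Hcn2, Dcn, Dpt, Sdhb, Hk1 and Pfkfb2 were lost without at least 1 library, with a highest adjusted p = 0.22 for Pfkfb2 (without the first KO library). The lists of excitation (0.11) and fibroblasts (0.18) were lost without the first WT library, and the glucocorticoid list (0.15) without the third.

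**Figure D2:**
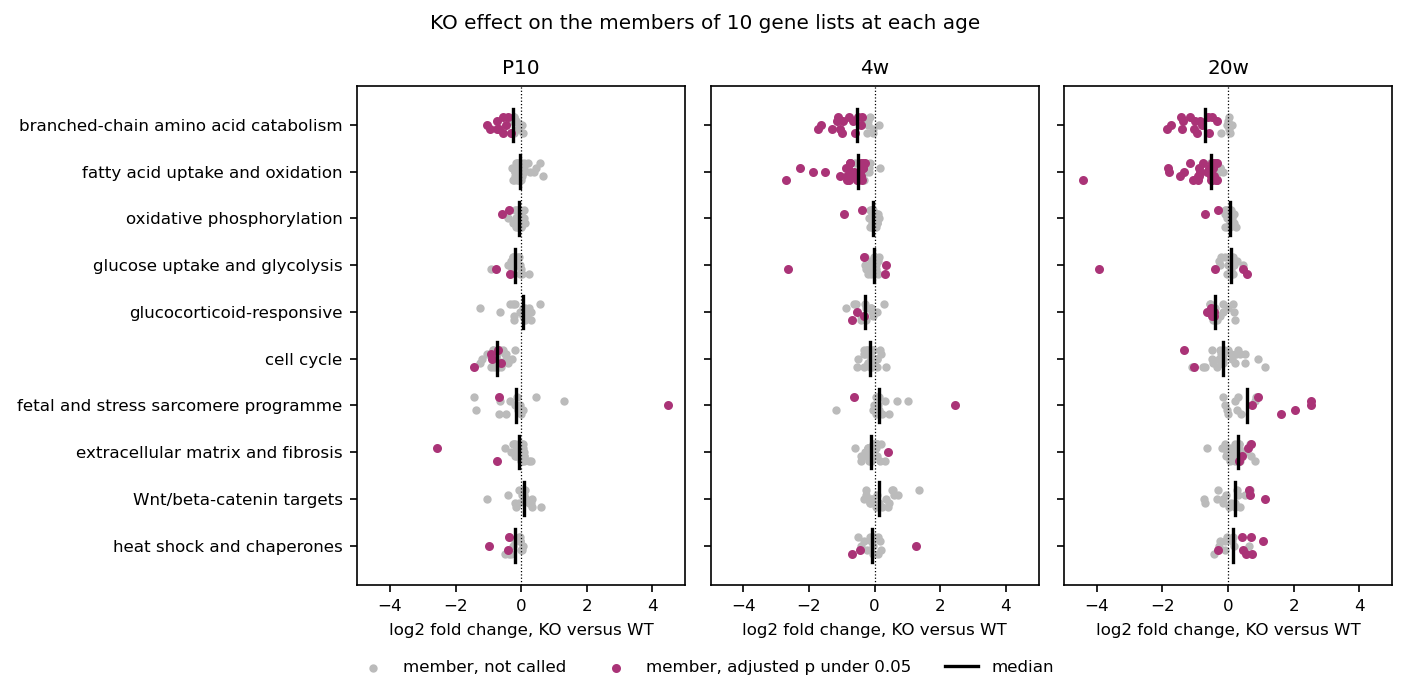
Log2 fold change between KO and WT for each tested member of 10 gene lists at the 3 ages, with called members in purple, the others in grey and a black line at the median. The median of fatty acid uptake and oxidation was -0.05 at P10, -0.51 at 4w and -0.52 at 20w.

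At 20w the fatty acid and branched-chain lists were lower in KO hearts as at 4w, and Nppb and Ankrd1 were higher. Of the 35 fatty acid genes 29 fell and none rose (33 fell adjusted over the list alone; camera adjusted p = 1.9e-36; adjusted p = 0.03 with an estimated correlation). Acot1 fell from 111.1 ± 20.3 to 4.5 ± 2.7 (-4.42 ± 0.32 SE, adjusted p = 9.2e-09), Acot2 was 2.24-fold lower, Acaa2 2.07-fold and Echs1 1.85-fold. Of the 22 branched-chain genes 15 fell and none rose (16 adjusted over the list alone; camera adjusted p = 1.2e-23; adjusted p = 0.03 with an estimated correlation). Aldh6a1 was 3.59-fold lower, Bckdhb 3.35-fold, Bcat2, the mitochondrial branched-chain aminotransferase, 2.71-fold and Dbt 2.64-fold. In the fetal and stress sarcomere programme 6 of 16 members rose and none fell (camera adjusted p = 7.8e-05; adjusted p = 0.21 with an estimated correlation). Nppb, which encodes B-type natriuretic peptide, rose from 570.0 ± 59.3 to 3435.0 ± 1205.7 (2.54 ± 0.33 SE, adjusted p = 4.4e-05). Myh7 rose from 2994.2 ± 290.5 to 17391.0 ± 3441.8 (2.52, adjusted p = 0.027), the mechanical stress gene Ankrd1 from 16425.5 ± 1057.7 to 52430.4 ± 20650.6 (1.61, adjusted p = 0.00041) and the calcineurin regulator Rcan1 from 867.1 ± 118.6 to 1677.3 ± 539.7 (0.91). Acta1, the skeletal alpha actin, was at 10714.7 ± 9312.5 in KO against 2058.3 ± 539.1 (2.05, adjusted p = 0.023).

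Other genes with high fold changes at 20w were Tnfrsf12a, the receptor of the cytokine TWEAK (150.1 ± 39.2 to 627.7 ± 308.8, 1.97, adjusted p = 0.00019), and the sodium/calcium-potassium exchanger Slc24a2 (84.3 ± 7.5 to 313.5 ± 132.6, 1.81). Rprl3 had a value of 6.73, with the uncertainty given above. Adhfe1 had the lowest fold change at 20w (-6.14). Other low values were those of Klf15, Acot1, Abhd1 (-4.15) and Abat, the GABA transaminase (635.9 ± 30.1 to 36.5 ± 2.9, -4.09 ± 0.15 SE, adjusted p = 1.7e-13). Pfkfb1 fell from 297.2 ± 69.8 to 19.0 ± 7.9 (-3.94) and Pfkfb2 rose 1.49-fold. With 2 of its 21 genes higher and 2 lower, the glucose list did not pass (adjusted p = 0.63), and its median (0.09) and mean (-0.11) differed in sign. Heat shock and chaperones had 6 of 17 members higher and 1 lower. Hspb8 rose 1.46-fold, Hspb1 2.11-fold, Hsph1 1.64-fold and Cryab 1.35-fold (camera adjusted p = 0.025; adjusted p = 0.57 with an estimated correlation). Glucocorticoid-responsive genes had 5 of 19 lower, among them Klf9 (1.34-fold), Tsc22d3 (1.43-fold) and Sult1a1 (1.34-fold) (camera adjusted p = 7.8e-05; adjusted p = 0.21 with an estimated correlation). Of 19 clock genes 4 fell and 1 rose, with Per3 1.43-fold, Per2 1.58-fold, Hlf 1.58-fold and Tef 1.27-fold lower (camera adjusted p = 0.064). The calls of Per3 (limma adjusted p = 0.063) and Tef were lost with a common total. Those of Hlf (0.13) and Tef were lost without the 4 libraries highest in Rn45s. In the excitation list 4 of 22 rose and 3 fell, with Hcn2 at 0.71 and Kcnv2 at -1.17, and the list did not pass (adjusted p = 0.91).

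Extracellular matrix and fibrosis genes had 4 of 34 members higher at 20w, Fbn1 (1.63-fold), Loxl1 (1.52-fold), Col6a2 (1.35-fold) and Col4a2 (1.25-fold) (camera adjusted p = 7.8e-05; adjusted p = 0.57 with an estimated correlation). Some lists of cell type markers passed camera with the preset correlation as well, although 3 of 10 splits of the libraries called as many lists as the real 9. Cardiomyocyte markers had 4 of 15 higher, Mybpc3 (1.45-fold), Pgam2 (1.38-fold), Csrp3 (1.36-fold) and Ckm (1.38-fold) (camera adjusted p = 0.00081; adjusted p = 0.43 with an estimated correlation). Fibroblast markers had 3 of 14 higher, Pi16 (1.6-fold), Mfap4 (1.74-fold) and Mfap5 (1.75-fold), without passing as a list (adjusted p = 0.32). Macrophage markers moved up with no called member among 18 (median 0.24, adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation), with Adgre1 at 0.4 (adjusted p = 0.074). Atrial markers moved down with none of 8 called (median -0.45, adjusted p = 0.027; adjusted p = 0.49 with an estimated correlation), with Myl4 at -0.54 (adjusted p = 0.088) and Bmp10 at -3.16 (51.4 ± 79.6 in WT, 0.5 ± 0.8 in KO, adjusted p = 0.16). Among Wnt lists, 3 of 19 targets rose (Shisa3, which the series title names, Cd44 at 1.6-fold and Bambi at 1.56-fold; camera adjusted p = 0.32). Among 18 ligands and receptors Fzd1 (1.37-fold) and Wnt5b (2.19-fold) rose and Fzd4 fell (1.19-fold; adjusted p = 0.63). Among 9 secreted antagonists Dkk3 (1.45-fold) and Sfrp5 (2.82-fold, from 25.8 ± 10.1 to 8.8 ± 5.1) fell (adjusted p = 0.63).

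In all, 976 genes were called at 20w, 418 higher and 558 lower, and 408 with libraries scaled to a common total (31.4% higher against 42.8%). Without single libraries the count was 581 (without the third KO library) to 1165. The third KO library held the highest Nppb (4816.2) and Tnfrsf12a (962.9). Without it, the lists of extracellular matrix (adjusted p = 0.24), heat shock (0.21), macrophages (0.078) and the atria (0.11) no longer passed, and neither did Acta1 (0.15), Myh7 (0.094), Cd44 (0.19), Bambi (0.24), Fzd1 (0.18), Wnt5b (0.12), Sfrp5 (0.17), Fbn1 (0.071), Loxl1 (0.22), Col6a2 (0.23), Col4a2 (0.24), Mfap4 (0.13), Mfap5 (0.17), Csrp3 (0.11), Ckm (0.062), Cryab (0.067), Kcnv2 (0.055) and Sult1a1 (0.092). Several of these calls did not depend on that library alone. Those of Myh7, Fzd1, Col6a2 and Col4a2 were lost without any of 5 of the 6 libraries, and those of Wnt5b, Sfrp5, Sult1a1 and Ckm without any of 4. The highest adjusted p was 0.22 for Wnt5b and 0.17 for Sult1a1 (without the third WT library) and 0.14 for Ckm (without the second KO library). Other single libraries ended the calls of Fzd4 (adjusted p = 0.16 without the second WT library), Tef (0.057 without the first), and Tsc22d3 (0.074) and Pgam2 (0.059) without the third.

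Averaged over the 3 ages, among called genes with a mean of at least 50 and groups that did not overlap at any age, the lowest fold changes were those of Adhfe1 (-5.6 ± 0.12 SE, adjusted p = 2.6e-17), Klf15 (-4.01), Abhd1 (-3.06), Bdnf (-2.84), the glutathione S-transferase gene Gstk1 (-2.46) and Abat (-2.2). Myh7 (3.15) and Rprl3 (6.07) were higher on average, but their groups overlapped at 4w. The highest under these limits were those of Pygl (1.49 ± 0.09 SE, adjusted p = 2.5e-10), Plekhh1 (1.01), the telomere-capping subunit gene Ten1 (0.91), Lad1 (0.84), Whrn (0.71) and the transcription factor gene Sox4 (0.7). In the branched-chain list 16 of 22 members fell and in the fatty acid list 31 of 35, none rose in either, and both had an adjusted p = 0.021 with an estimated correlation (camera adjusted p = 2.4e-30 and 2.5e-35). In all 1351 genes were called, 556 higher and 795 lower. The count was 706 without the 4 libraries highest in Rn45s and 826 with a common total, where 11% of calls were higher against 41.2%.

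Calls were shared between ages. The ages have no library in common, but all calls use the same estimate of the spread per gene. The calls are therefore not independent, and the numbers for independent lists are only a reference. Between 4w and 20w, 231 genes were lower at both ages, where independent lists of those sizes would share 14.8, and 73 were higher at both, against 12.5. Between P10 and 4w, 66 were lower at both against 5.8 and 16 higher against 2.3. Between P10 and 20w the numbers were 69 against 9.3 and 15 against 2.5. At all 3 ages 54 genes were called lower and 8 higher, and none with mixed signs. Klf15, Adhfe1, Abhd1, Abat, Bdnf, Gstk1, Bcat2, Bckdhb, Dbt, Ivd, Mut, Aldh6a1 and Cox6a2 were among the lower ones, and Myh7, Pygl, Plekhh1 and Rprl3 among the higher. Across all genes the fold changes at 4w and 20w correlated with r = 0.48 (Spearman 0.3), those at P10 and 4w with 0.29 (0.19) and those at P10 and 20w with 0.23 (0.06), where genes are not independent replicates.

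**Figure D3:**
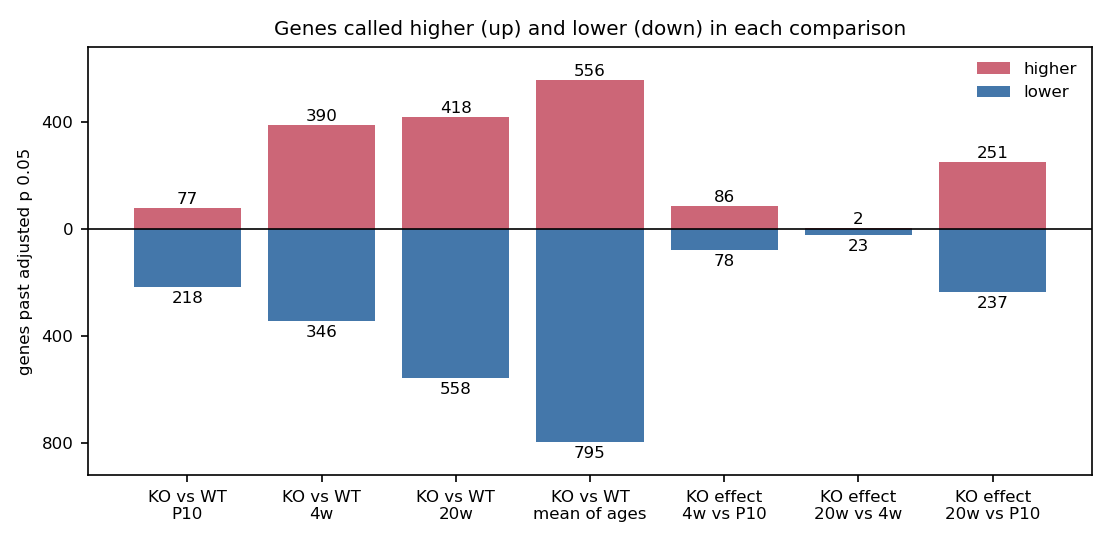
Number of genes called higher (above 0) and lower (below 0) in KO versus WT at each age and averaged, and in the 3 comparisons of the KO effect between ages. The KO effect differed in 488 genes between 20w and P10 and in 25 between 20w and 4w.

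The KO effect was compared between ages as the difference itself. From P10 to 4w it moved down for several enzyme genes. The proline dehydrogenase gene Prodh differed by -2.04 ± 0.23 SE (adjusted p = 0.00025), Gstm2 by -3.08, Gstk1 by -1.71 and the mitochondrial aldehyde dehydrogenase gene Aldh2 by -1.1 (adjusted p = 0.00027 each). It moved up for Phlda1 (1.93), the HIF prolyl hydroxylase gene Egln3 (1.11), the RNA-binding protein gene Pcbp2 (0.87) and B3galt2 (1.69). Of the fatty acid genes 13 of 35 had a lower KO effect at 4w than at P10 and none a higher one (camera adjusted p = 4.8e-29; adjusted p = 0.084 with an estimated correlation), and of the branched-chain genes 3 of 22 (7.3e-08; adjusted p = 0.57 with an estimated correlation). In all 164 genes were called, 86 higher and 78 lower. The count was 21 without the 4 libraries highest in Rn45s and 65 without the first 4w KO library, and with a common total 6.5% of 92 calls were higher against 52.4%.

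Between 20w and P10 the KO effect differed in 488 genes, 251 higher and 237 lower. Abat (-3.52 ± 0.21 SE, adjusted p = 4e-09), Acot1 (-4.29) and Zfp275 (-1.23) were among those lower. The chaperone genes Hspa4l (0.98 ± 0.1 SE, adjusted p = 2e-05) and Hspb8 (0.85), Sh2d4a (1.28) and the alkaline phosphatase gene Alpl (1.15) had the smallest adjusted p among those higher. The list of fatty acid genes had 15 of 35 lower (camera adjusted p = 4.8e-27; adjusted p = 0.11 with an estimated correlation), the branched-chain list 8 of 22 lower (1.2e-07; 0.29 with an estimated correlation), heat shock 6 of 17 higher (2.4e-05; 0.29) and the fetal and stress sarcomere programme 4 of 16 higher (0.00011; 0.29). Cardiomyocyte markers had 2 of 15 higher (0.03; 0.51 with an estimated correlation) and extracellular matrix 1 of 34 (1.1e-05; 0.42). The count was 161 with a common total and 276 without the second P10 WT library.

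Between 20w and 4w 25 genes were called, 2 higher and 23 lower. Abat had a KO effect 2.16 lower at 20w (± 0.21 SE, adjusted p = 2.3e-05). The KO effects on Pcbp2 (-0.96), Ubqln2, a ubiquitin-binding shuttle factor gene (-0.92), and Polr2a, the largest subunit of RNA polymerase II (-0.77), were also lower, and those on the receptor gene Met (1.57) and on Lmod3 (0.49) higher. For Pcbp2, Ubqln2 and Polr2a the 4w WT level lay below that of both other ages, for example 478.9 ± 9.4 for Polr2a at 4w against 1100.9 ± 174.2 at P10 and 1096.7 ± 53.5 at 20w. The count was 3 without the second 4w WT library, 113 without the second 20w KO library and 185 with a covariate from the residuals. The calls of Met, Lmod3 and Polr2a were each lost without some of the libraries (highest adjusted p = 0.13 for Met, 0.15 for Lmod3 and 0.12 for Polr2a). With a common total the calls of Pcbp2 (-0.72, adjusted p = 0.17), Ubqln2 (-0.68, adjusted p = 0.28), Polr2a and Lmod3 were lost, and 83.3% of 12 calls were higher against 8.0%. Pcbp2 also lost its call without the 4 libraries highest in Rn45s, and Ubqln2 with the replicate block.

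**Figure D4:**
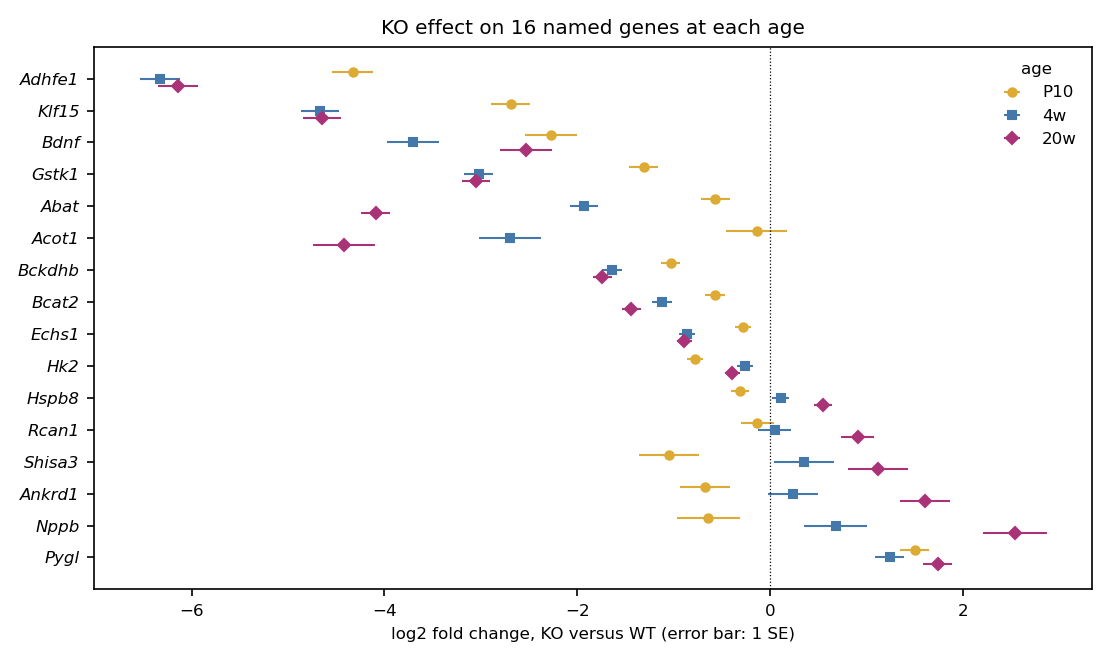
Log2 fold change between KO and WT with its standard error for 16 named genes at P10 (yellow circles), 4w (blue squares) and 20w (purple diamonds). The value of Abat moved from -0.57 at P10 to -1.93 at 4w and -4.09 at 20w, and that of Nppb from -0.64 to 0.68 and 2.54.

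From P10 to 4w, WT hearts differed in age and also in Xist, so both can enter this comparison. All 22 branched-chain genes rose (camera adjusted p = 3.7e-13; adjusted p = 0.08 with an estimated correlation), as did all 30 of oxidative phosphorylation (5.9e-14; adjusted p = 0.14 with an estimated correlation), while all 30 cell cycle genes fell (3.8e-15; adjusted p = 0.08 with an estimated correlation). Ces1d, a lipid carboxylesterase gene, rose from 30.1 ± 8.8 to 1817.6 ± 166.7 (5.91 ± 0.19 SE, adjusted p = 3.3e-14), and Gsta3 (5.2), Bdh1 (5.17), Cngb3 (4.66) and the retinol acyltransferase gene Lrat (4.64) rose as well. Esr1 had the highest value (7.9), from the 3 libraries given above. Tnni1, the slow skeletal troponin I of the fetal heart, fell from 1284.3 ± 702.3 to 8.5 ± 6.4 (-7.32), and low values were also those of Spon2 (-4.99), Igf2bp3 (-4.92), Ccnb1 (-4.49) and Nrk (-4.45). Xist fell by 11.93 on the log2 scale. Of 34 matrix genes 27 fell and 2 rose (camera adjusted p = 3e-11; adjusted p = 0.14 with an estimated correlation), and of 19 glucocorticoid-responsive genes 15 rose and 3 fell (1.3e-06; adjusted p = 0.08 with an estimated correlation). Macrophage markers rose in 16 of 18 (7.4e-07; adjusted p = 0.08 with an estimated correlation) and cardiomyocyte markers in 13 of 15 (2.3e-05; adjusted p = 0.14 with an estimated correlation). In all 7555 genes were called, 3746 higher and 3809 lower, and with a common total the median of all genes moved to -0.257.

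From 4w to 20w, Ano5 rose from 2.0 ± 1.8 to 145.9 ± 74.6 (5.78 ± 0.59 SE, adjusted p = 1.5e-06) and the cadherin gene Cdh4 from 6.9 ± 2.1 to 150.1 ± 20.0 (4.29), and high values were also those of Cpxm2 (3.21), Acsm5 (2.93) and the immediate early gene Egr3 (2.68). Esr1 (-6.68), Lrat (-4.41), Rprl3 (-2.99), the histone H1 genes Hist1h1b (-2.23) and Hist1h1a (-2.2), and the cytokinesis gene Prc1 (-2.17) fell. The Esr1 value again came from the unequal 4w WT libraries given above. Of 34 matrix genes 25 fell and none rose (camera adjusted p = 1.1e-15; adjusted p = 0.16 with an estimated correlation), and of 30 cell cycle genes 22 fell (5.8e-13; 0.14 with an estimated correlation). Fibroblast markers fell in 9 of 14 (2.9e-06; 0.12 with an estimated correlation) and macrophage markers in 12 of 18 (2.4e-05; 0.12), while atrial markers rose in 6 of 8 (0.018; 0.53 with an estimated correlation). Among branched-chain genes 11 of 22 rose and 1 fell (2.8e-05; 0.51 with an estimated correlation). In all 3273 genes were called, 1736 higher and 1537 lower, and 1771 with a common total (22.9% higher against 53.0%). The call of Egr3 was lost without the first 20w WT library (1.67, adjusted p = 0.06), and that of Rprl3 without the second 4w WT library (-1.08, adjusted p = 0.18).

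Whether the KO differences lay along or against the change that WT hearts make with age was examined with a correlation across genes, between the KO effect at an age and the WT change between the other ages. Pearson's r was 0.019 at P10, -0.149 at 4w and -0.113 at 20w. The two-sided exact permutation p was 0.9, 0.6 and 0.3 (0.9 each after adjustment over the 3 ages). With 10 splits of 6 libraries the smallest p possible is 0.1, so this design could not reach significance. Splits other than the real one gave an absolute r of up to 0.204, 0.403 and 0.135.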

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

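The genes and lists here were picked by a fixed rule, a KO effect that differed between 2 ages in a test of the difference itself. The rule was applied to the genes and lists discussed here, and which lists and members are discussed was chosen after the results were seen. Each is given only for the pair of ages with its smallest adjusted p. The genes and lists under a pair of ages are therefore not complete, and some also differed between another pair. The GC content and length test, the test of strain segments and the breakdown of splits were also chosen after the results were seen. Groups of 3 libraries were not tested for single outlying libraries. Values are differences of the KO effect on the log2 scale, later age minus earlier age, each with a limma adjusted p under 0.05.

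Between 20w and P10, the KO effect was lower at 20w for these genes: Acot1 -4.29, Abat -3.52, Gstm2 -3.37, Pfkfb1 -3.02, Adhfe1 -1.81, Gstk1 -1.75, Prodh -1.75, Acot2 -1.25, Slc27a1 -1.24, Aldh2 -1.06, Acaa2 -1.05, Aldh6a1 -0.91, Bcat2 -0.88, Slc25a20 -0.73, Dbt -0.73, Bckdhb -0.71, Ivd -0.63 and Echs1 -0.61. The same held for Klf15 (-1.95), Zfp275 (-1.23), Rph3al (-1.04), Per2 (-0.77), Dkk3 (-0.7), Klf9 (-0.6), Per3 (-0.6) and Abcc9 (-0.37).

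The KO effect was higher at 20w than at P10 for these genes: Acta1 3.43, Nppb 3.18, Ankrd1 2.27, Shisa3 2.17, Tnfrsf12a 2.05, B3galt2 1.68, Slc24a2 1.67, Atp6v0e2 1.32, Sh2d4a 1.28, Ten1 1.22, Trim54 1.21, Met 1.18, Hspb6 1.16, Alpl 1.15, Hspb1 1.11, Col8a1 1.1, Hsph1 1.08, Rcan1 1.04, Hspa4l 0.98, Hspb8 0.85, Cryab 0.81, Hcn2 0.75, Pgam2 0.73, Mybpc3 0.59, Pfkfb2 0.56 and Lmod3 0.55.

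Between 4w and P10, the KO effect at 4w was lower for Esr1 (-6.08), Bdh1 (-1.99), Adra1a (-1.86) and Sult1a1 (-0.74). It was higher for Cyfip2 (3.18), Phlda1 (1.93), Hspa8 (1.23), Egln3 (1.11), Polr2a (0.65), Rrm1 (0.58) and Hk2 (0.52). The Esr1 value rests on 4w WT libraries that held 30245.9, 5205.2 and 345.6, while every other library held at most 77.1. The Cyfip2 value rests partly on 4w WT libraries that held 894.5, 1469.0 and 4178.6, which overlap the 4w KO libraries (791.5 to 1826.2). Between 20w and 4w it was lower for Pcbp2 (-0.96) and Ubqln2 (-0.92), both not called with a common total (adjusted p = 0.17 and 0.28). Abat, given above for 20w versus P10, was also called lower for 20w versus 4w. Gstm2, Prodh, Gstk1 and Aldh2 were also called lower for 4w versus P10.

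Among gene lists, the median difference between 4w and P10 was -0.44 for fatty acid uptake and oxidation (adjusted p = 0.084 with an estimated correlation), -0.28 for branched-chain amino acid catabolism (0.57), 0.31 for interferon response (0.71) and 0.58 for the cell cycle (0.57). Between 20w and P10 it was 0.55 for the fetal and stress sarcomere programme (0.29), 0.48 for macrophages (0.14), 0.3 for heat shock (0.29), 0.25 for glucose uptake and glycolysis (0.37), -0.24 for the circadian clock (0.36) and -0.32 for glucocorticoid-responsive genes (0.29). Between 20w and 4w it was -1.03 for atrial markers (0.28), 0.39 for extracellular matrix (0.54), 0.22 for cardiomyocytes (0.54), 0.21 for fibroblasts (0.28) and 0.09 for oxidative phosphorylation (0.84). The p in brackets is the adjusted p with an estimated correlation throughout, and none of these lists passed with it.

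The genes called in KO versus WT averaged over ages could come from loss of Klf15 or, if the allele was made in another strain, which the sources used here do not give, from DNA of that strain. Within 10 Mb of Klf15, 17 of 128 tested genes were called (13.3%) against 1331 of 12849 elsewhere (10.4%). The ratio was 1.28 (Fisher exact p = 0.31), so no concentration of calls near Klf15 was detected. Of the calls 93.8% lay on other chromosomes, which says little because so few tested genes lie near Klf15. Passenger DNA near Klf15 therefore does not explain the calls as a set. The 17 genes called there, which include Klf15 itself and Hk2, were not cleared one by one. Segments elsewhere in the genome remain open, because 125 neighbouring pairs were called in the same direction, against a median of 64 and a highest value of 90 in 1000 random draws. The pairs over the random median were 3.67 times at P10, 1.94 at 4w and 2.28 at 20w for KO versus WT, against 1.16 and 1.21 for the WT age comparisons. Neighbouring genes can also share regulation, and the comparisons differ in their number of calls, so the explanations were left open.

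The genes whose KO effect differed between 20w and 4w could rest on properties of the 4w libraries. Over 12930 genes, the difference of the KO effect between 20w and 4w had a Spearman correlation of -0.29 with transcript length and 0.06 with GC content. The KO effect itself correlated with GC content at 0.23 at P10, 0.11 at 4w and 0.16 at 20w. With length the correlations were 0.05, 0.18 and -0.16, so their sign differed between 4w and 20w. With GC content and length trends removed, 96% of the 25 genes were still called (24), with a median absolute log2 change of 0.74 against 0.88. Without the second 4w KO library, which is rich in ribosomal RNA, the median absolute log2 change kept 95.4% of its size and all 25 kept their sign, but 5 were still called with fewer libraries. For the 736 genes called in KO versus WT at 4w, the size kept without that library was 100.2%, with 425 still called. GC content and length trends therefore do not explain most of the size of the 25 differences. Whether ribosomal RNA in the second 4w KO library contributed to the calls or their sizes was not decided. Genes called with that library included already tend to agree across their group, so their sizes could hardly fall without it. The split test below did not exclude chance for the count of 25.

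The genes called in KO versus WT at P10 could reflect a different share of female tissue in the WT and KO libraries. With the log2 Xist value as a covariate the median absolute log2 change kept 108.1% of its size, all 295 genes kept their sign, and 177 were still called. Genes called without the covariate already tend to agree within their group, so their sizes could hardly fall with it. Whether the share of female tissue contributed to the calls was therefore not decided. Loss of Klf15 and inherited strain segments remain open as well, since at P10 11 neighbouring pairs were called in the same direction, against a median of 3 and a highest value of 10 in the random draws.

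The libraries were also regrouped between the groups compared. For the comparisons at a single age 10 splits exist, which are too few for a share under 0.05. As many genes as in the real grouping were called in 1 split, the real one, at P10 (295, highest other 4), at 4w (736, highest other 10), at 20w (976, highest other 9) and in both WT comparisons (7555 and 3273, highest other 0). For lists, 4 splits at P10 called as many as the real 9 (highest other 13), 10 at 4w as many as 5 (highest other 11) and 3 at 20w as many as 9 (highest other 9). The number of lists called therefore does not separate the real grouping from the others at any age. For the average over ages, 1 of 100 splits, the real one, called as many genes (1351, highest other 195). In 81 of the 100 the labels were opposed between ages, so that a real KO effect would largely cancel (highest 8). The splits with labels oriented alike at all ages are too few for a share under 0.05, so chance was not excluded here either. For the differences between ages, as many genes were called in 2 of 100 splits for 4w versus P10 (164, highest other 192). The same held for 2 of 100 for 20w versus P10 (488, highest other 646) and 6 of 100 for 20w versus 4w (25, highest other 332). These splits regroup WT and KO within each age and do not keep an equal KO effect at both ages. They therefore cannot decide whether the KO effect differs between ages by more than chance. In the highest other splits of these differences, 1 age kept its real grouping while libraries of the other age were mixed, so the KO effect itself entered the difference.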

How the results depend on the processing

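Among the named genes, 156 of 243 called results kept their call under every setting and none changed sign. Of 435 values for the 19 uncalled results, 54 were called and none changed sign. Klf15 kept its call at every age under every setting. The GC content and length, residual component and Rn45s settings were chosen after seeing the data. Except where fewer genes, fewer libraries or a stricter threshold are named, the cause was not tested.

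Counts of called genes that moved by more than 1.5 times are given by setting, in the order of the comparisons. Without a filter on low values (more genes tested) they were 183 at P10 and 7 for the KO effect at 20w versus 4w. Upper quartile scaling gave 8 and quantile normalization 7 for 20w versus 4w. With a common total they were 109 at P10, 408 at 20w, 826 averaged, 92 for 4w versus P10, 12 for 20w versus 4w, 161 for 20w versus P10 and 1771 for WT 20w versus 4w. With only the libraries compared they were 466 at P10 and 64 for 20w versus 4w. With library quality weights they were 1384 at P10, 566 for 4w versus P10, 90 for 20w versus 4w and 1004 for 20w versus P10. The Xist covariate gave 104 for 4w versus P10 and 47 for 20w versus 4w. Without the trend they were 173 at P10, 78 for 4w versus P10, 3 for 20w versus 4w and 323 for 20w versus P10. With edgeR they were 515 at P10 and 15 for 20w versus 4w, and with DESeq2 562 at P10, 331 for 4w versus P10 and 157 for 20w versus 4w. With GC content and length trends removed they were 276 for 4w versus P10 and 48 for 20w versus 4w. With the residual component they were 450 at P10, 314 for 4w versus P10, 185 for 20w versus 4w and 751 for 20w versus P10. Without the 4 libraries highest in Rn45s (fewer libraries) they were 193 at P10, 212 at 4w, 473 at 20w, 706 averaged, 21 for 4w versus P10, 5 for 20w versus 4w, 298 for 20w versus P10 and 1750 for WT 20w versus 4w. With an absolute log2 fold change of at least 1 they were 54 at P10, 89 at 4w, 198 at 20w, 78 averaged, 51 for 4w versus P10, 5 for 20w versus 4w, 163 for 20w versus P10, and 1913 and 490 for WT. At an adjusted p under 0.01 they were 100, 309, 433, 686, 44, 3 and 149 for the KO comparisons in that order and 1703 for WT 20w versus 4w.

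The labels do not say whether replicate numbers pair the libraries. Same-numbered WT and KO libraries had residual correlations of -0.25, -0.09 and -0.06 at P10, 0.06, 0.12 and -0.1 at 4w, and -0.11, -0.02 and -0.01 at 20w. The second library nevertheless had the highest shares of Rn45s and Lars2 in every group, for Rn45s 0.574% in P10 WT and 0.85% in P10 KO. The number may therefore mark a shared trait of the libraries, and 3 libraries per group are too few to exclude it. With the replicate number as a block the counts were 171 at P10, 470 at 4w, 67 for 4w versus P10, 3 for 20w versus 4w and 275 for 20w versus P10, and Shisa3 at 20w was not called (1.12). Shisa3 at P10 gained a call with library weights (-0.75), the Xist covariate (-1.47), edgeR (-1.16), DESeq2 (-1.12) and the residual component (-1.05). At 20w it lost the call without a filter (1.12), without the trend (1.12), with edgeR (1.14) and without the 4 libraries highest in Rn45s (1.19). With an estimated correlation 0 lists were called at P10, 2 at 4w and 2 at 20w. At 4w 12 lists were called with a common total, 3 without the trend and 3 with edgeR. The maturation correlation at P10 (0.019) reversed with Spearman (-0.002), without P10 WT replicate 2 (-0.035) and without P10 KO replicate 3 (-0.019).

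Leaving out single libraries (fewer libraries), the counts ranged from 110 to 295 at P10, 373 to 675 at 4w, 581 to 1165 at 20w, 1055 to 1755 averaged, 65 to 234 for 4w versus P10, 3 to 113 for 20w versus 4w, 276 to 594 for 20w versus P10, 6688 to 7289 for WT 4w versus P10 and 2348 to 2880 for WT 20w versus 4w. Klf15 ranged from -2.79 to -2.53 at P10, -4.88 to -4.42 at 4w and -4.72 to -4.51 at 20w, and Shisa3 from -1.31 to -0.78, 0.1 to 0.74 and 0.86 to 1.29. Lists called ranged from 7 to 9, 5 to 7 and 6 to 9, and the maturation correlation from -0.035 to 0.073, -0.277 to -0.045 and -0.14 to -0.085. With 3 libraries per group and at least 9504538 reads each, the simulated recovery of changes of log2 1 was 72% at P10 and 80% at 4w and 20w, so smaller changes are missed more often.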

Other observations

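Which of the following lists and libraries are described was chosen after the results were seen. In the matrix list at P10, Spp1, which encodes osteopontin, fell by 2.58 on the log2 scale (adjusted p = 0.0022) and Col8a1 by 0.74 (adjusted p = 0.04), without passing as a list (adjusted p = 0.16). At 4w Fn1 rose by 0.42 (adjusted p = 0.047; list adjusted p = 0.23). The muscle ring finger gene Trim54 fell by 0.89 at P10, Trim55 rose by 0.33 at P10 and 0.42 at 4w, the proteasome gene Psmd11 rose by 0.44 at 4w and the autophagy receptor gene Sqstm1 by 0.36 at 20w. Their list of atrophy and the ubiquitin-proteasome system did not pass (adjusted p = 0.91, 0.71 and 0.085 at P10, 4w and 20w).

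In the vascular growth list Notch1 rose by 0.32 at 4w, and at 20w Aplnr rose by 0.59 and Pgf fell by 0.74, without a list call (adjusted p = 0.8, 0.05 and 0.63). Mybpc2 fell by 0.67 at P10 and 0.63 at 4w, and Cspg4, a pericyte marker, rose by 0.5 at 4w. The cell cycle list did not pass at 4w (adjusted p = 0.23) or 20w (0.11), although Rrm2 fell by 1.05 and Bub1 by 1.33 at 20w. Leaving out single libraries ended the calls of Col8a1 (adjusted p = 0.19), Fn1 (0.25), Trim55 at P10 (0.18), Sqstm1 (0.052), Notch1 (0.14), Aplnr (0.1), Pgf (0.14), Mybpc2 (0.14 and 0.091), Cspg4 (0.14) and Bub1 (0.11).

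No member was called at any age among immediate early genes (list adjusted p = 0.55, 0.41 and 0.63 at P10, 4w and 20w), endothelial markers (0.18, 0.79 and 0.32) and nerve and Schwann cell markers (0.91, 0.23 and 0.67). The integrated stress response list had 1 of 19 members lower at 20w (0.46, 0.36 and 0.97) and mesothelium and epicardium 1 of 6 higher at 20w (0.46, 0.68 and 0.97).

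Ifi202b separated the genotypes at P10 and 20w, at 0 in all KO libraries and between 23.4 and 83.1 in all WT libraries. At 4w it was 0 in the first WT and the first KO library, and lay between 16.2 and 89.3 in the others. Some single 4w libraries also stood apart from their group. No explanation was tested for these values or those below. Nnt was at 7942.7 in the first 4w WT library, against 20806.6 and 21123.6 in the other two. The same library held 149.8 of Sun3, against 10.7 and 7.0. Cyfip2 was at 894.5, 1469.0 and 4178.6 in the 4w WT libraries. Rprl3 was at 464.6 in the second 4w WT library, against 6.7 and 9.3 in the others, and Myh7 at 13491.4 against 803.5 and 1040.3.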
